A study of Caenorhabditis elegans with 2 samples.

How the data were processed

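Chromatin immunoprecipitation and sequencing of ZTF-11 was done on whole L2 larvae of strain OP236, in 2 biological replicates, per the labels. Chromatin was sheared by sonication, per the labels. Per the file headers, that is the text notes deposited with each sample, the authors called regions on the alignments of each replicate and of both replicates pooled, each time with a control, kept long lists of peaks together with background, and derived a thresholded "optimal" set from the pooled list and both replicate lists by the irreproducible discovery rate (IDR). The aligner, the caller, their versions and the IDR threshold are not given in the sources used here. The regions were deposited on ce11 and on ce10.

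The deposited score of each region is the authors' signal value, relative to the control, on a scale that is not given in the sources used here. It is each region's own value and was used only to describe and rank regions within a list and to set both replicates side by side at the same peaks. The deposited −log10 of the q value saturates at the top of each list and has 1 value, 1.65, for the whole thresholded set, so it ranked nothing. The deposited summit offset gave each region's summit. The ce11 lists held 30000 regions for each replicate, 20223 pooled and 210 thresholded (207 distinct regions, a few with more than 1 summit). Mapped reads, and so the depth of each sample, are unknown. How reads that fit several places were handled is not given in the sources used here, which matters for multicopy genes and for the mitochondrial genome. The intervals given cover counting error only.

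Replicates were grouped by the biological replicate number in the labels. The reference was WBcel235, which has the coordinates of ce11, with the Ensembl release 115 annotation and the RefSeq sequence, and no region extended past a chromosome end. The ce10 lists were used for counts, overlaps and scores only, and no coordinate was converted. MicroRNA genes without a name in the annotation were found through RefSeq symbols at the same place.

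Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The tests, gene lists, alternatives and naming rule were fixed before the data were examined, except where the text says otherwise. Background regions were the 19978 regions of the pooled list that overlapped no thresholded peak. A promoter reached from 1500 bp upstream to 500 bp downstream of the 5′ end of a protein-coding gene, and a gene was called bound when a summit lay in it. Summits were assigned to promoter, 5′ UTR, coding exon, 3′ UTR, intron, noncoding exon or intergenic sequence in that order. Shares were compared with Fisher's exact test, peaks per chromosome with an exact binomial test against the background share, and replicates by the overlap of their top regions, where the summit of 1 region had to lie in a region of the other, with 1000 random placements for comparison. The 24 gene lists were tested among 19973 nuclear protein-coding genes, with microRNA genes added for the heterochronic and glia lists, and again with 10000 draws of background regions. Multiple tests were adjusted by Benjamini and Hochberg. 6-mers on either strand were scored for presence within 50 bp of the summit against 10 background windows per peak matched on GC content. The core AAAGTT was scored in the same window and in flanks centred 250 bp away.

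The core was first tested with a sign test against the mean of both flanks. On simulated data without an effect that test passed an unadjusted 0.05 in 93 of 200 sets of 210 peaks, because a peak counts for the flanks when either of them holds the core. It was replaced by an exact McNemar test against each flank, of which the larger p decides, and which passed in 0 of 200 such sets and in 195 of 200 sets with the core removed from 70% of summits. Other steps were tested on simulated data in the same way. The ribosomal protein and collagen lists, of 78 and 156 genes, were called in 80 of 80 cases with 12 planted genes each among 19973 genes. Of the unplanted lists 2 of 880 were called. Recovery in the shorter lists was not tested. A 6-mer planted in 15% of windows ranked first among 2080 in 10 of 10 runs.

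By the naming rule, the text was to name the 25 peaks of highest score with the genes whose promoters hold them or the nearest gene, up to 6 bound members of each list, ztf-11 and unc-119, and the 10 6-mers with the smallest adjusted p. Of the 25, 22 were mitochondrial, and the text departs from the rule by describing these as a group, with the position of the uppermost and no genes. The 25 highest nuclear peaks are given instead, by gene or by summit position, chosen after the values were seen. The lists for neurons, epidermis, body muscle, pharynx, intestine, germline and glia served as the markers of the tissues in a whole larva. Alternatives covered the promoter window, the background, the stronger 105 peaks, each replicate alone, merging of summits within 500 bp, leaving out the neighbourhoods of ztf-11 (40 kb) and unc-119 (10 kb), the overlap rule, the number of top regions, the build, the motif and its window, and the assignment of genes. Nuclear peaks alone and the chromosome counts of each replicate were added after seeing the data.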

Results

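ZTF-11 is a zinc finger protein of the MYT1 family, whose members are known as transcriptional repressors in developing neurons. Its binding was mapped by chromatin immunoprecipitation and sequencing in whole second-stage (L2) Caenorhabditis elegans larvae of both sexes, from strain OP236, an integrated line that expresses ZTF-11 fused at its C terminus to GFP and FLAG. There was 1 group of 2 biological replicates and no contrast between conditions, so the data describe where the tagged protein was enriched and how far the replicates resembled each other. The deposited values are regions with a signal score set against a control. Reads per sample are unknown, because the lists hold no read counts. All positions are on ce11, and p-values measure spread over regions or genes, not over animals.

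The authors' thresholded set held 210 peaks, of which 188 lay on the nuclear chromosomes and 22 on the mitochondrial chromosome. The mitochondrial peaks were the 22 of highest signal, with scores from 125.4 to 2033 and a median of 685.3. They covered 8282 of the 13794 bp of that chromosome, or 60.0%. The uppermost ranged from position 12643 to 13381 and had its summit in coding sequence. Nuclear peaks had scores from 32.9 to 116.3, with a median of 40.5, against a median of 11.7 for the 19978 background regions of the pooled list that overlapped no peak. Because the mitochondrial peaks alone filled the top of the ranking, the results on replicates, position and sequence are also given for the nuclear peaks, a choice made after their values were seen.

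**Figure D1:**
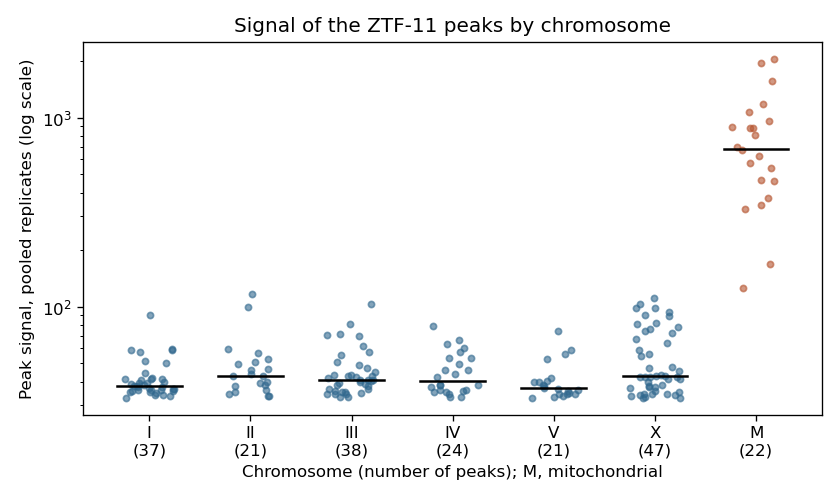
Signal score of each of the 210 peaks (points, log axis) by chromosome, with the number of peaks in brackets and the median as a black line; points are spread sideways for legibility. All 22 mitochondrial peaks (M) lie above the highest nuclear peak, at 116.3, and the X chromosome has the most nuclear peaks, 47.

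At the peaks, the heights in the replicates were only loosely related. A region of replicate 1 held the summit of 207 peaks, a region of replicate 2 held 203, and 200 peaks were in both lists. Presence in both is partly built in, since the set was derived from both lists and each list held 30000 regions. Of the 188 nuclear peaks 181 (96.3%) were in both, against 24.6% of background regions and 1.70% of randomly placed peaks. At these 181 peaks the median score was 23.6 in replicate 1 and 18.4 in replicate 2, and the ratio of replicate 1 to replicate 2 ranged from 0.73 to 2.30 between its 10th and 90th percentiles. Across all 200 peaks, which are not independent replicates, Spearman's rho was 0.46 and Pearson's r was 0.92. Over the nuclear peaks rho was 0.27 and r was 0.52, so the high r rested on the mitochondrial peaks. The nuclear peaks were selected by a threshold derived from both replicates. Such a selection narrows the range of scores and can by itself lower a correlation. Of the 210 highest-scoring regions of each replicate, 46.7% had a counterpart in the other, against 6.01% on average and at most 9.52% in 1000 random placements. For the 188 highest nuclear regions the shared portion was 40.4%, against at most 1.06%.

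**Figure D2:**
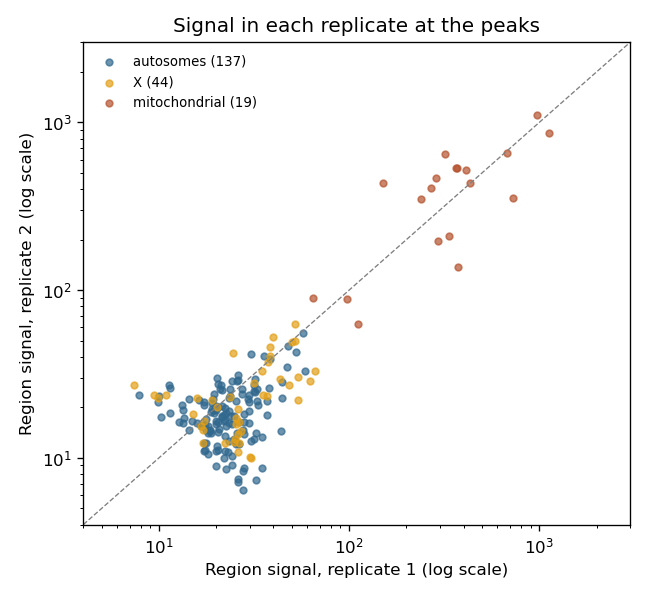
Signal score in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis) for the 200 peaks with a region in both lists; the dashed line marks equal scores. Mitochondrial peaks lie far up the diagonal, while nuclear peaks form a broad cloud with a Spearman's rho of 0.27.

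The tagged gene itself was not among the strong sites. ztf-11 (WBGene00009939, chromosome I, 9904303 to 9910545) held 1 peak within the gene, with its summit at 9908446 and a score of 34.1, which ranked 194 of 210. Within 40 kb of the gene the pooled list had 39 regions, against a mean of 17.4 ± 6.30 (SD) over 1159 windows of the same size across the genome, of which 4 held as many. Replicate 1 and replicate 2 each had 50 regions there, against means of 25.8 and 25.8. The integrated transgene carries ztf-11 sequence, and extra gene copies raise read density there. At this locus binding and copy number therefore cannot be told apart, for the peak or for the number of regions. unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935), the gene mutated in this strain and the usual rescue marker of such lines, held no peak, and its highest pooled region scored 12.8.

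ZTF-11 peaks lay mainly in promoters. Of the 188 nuclear peaks, 120 (63.8%) had their summit between 1500 bp upstream and 500 bp downstream of the 5′ end of a protein-coding gene, against 34.7% of background regions (odds ratio 3.32, Fisher's exact test, two-sided, p = 1.17e-15). With the mitochondrial peaks included the share was 66.2% (139 of 210, odds ratio 3.68, exact p = 3.60e-20), but the background holds no mitochondrial regions. Among the 120 promoter peaks, 111 lay upstream of the nearest 5′ end, the median distance was 214 bp, and 55 lay in the promoters of more than 1 gene. The promoter window reaches further upstream than downstream, so most peaks in it would lie upstream without any preference. The upstream share of background regions was not computed. Summits in introns made up 15.96% of nuclear peaks against 31.8% of background regions, and those in coding exons 0.53% against 8.66% (Fisher's exact test, adjusted p = 3.11e-06 for each, Benjamini-Hochberg over 7 classes). Intergenic summits made up 14.9% against 20.1%, which did not pass the exact test (adjusted p = 0.14).

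The X chromosome carried more peaks than its share of background, and fewer of them lay in promoters than on the autosomes. It held 47 of the 188 nuclear peaks (25%, 95% Wilson interval 19.4 to 31.6) against 16.8% of background regions, a 1.49-fold excess (exact binomial test, adjusted p = 0.025 over 6 chromosomes). Chromosome V held 21 peaks, 0.61 times its share (exact test, adjusted p = 0.025). Chromosomes I (37 peaks), II (21), III (38) and IV (24) did not pass, with adjusted p of 0.24, 0.29, 0.16 and 0.079. With the top regions of replicate 2 alone (without replicate 1) X had a 1.33-fold excess (exact test, adjusted p = 0.15) and V was at 1.00, and with those of replicate 1 alone they were at 1.36 and 0.65, past the threshold in neither. Without replicate 1, chromosome IV passed instead, at 0.55 times its share (exact test, adjusted p = 0.014). Of the 25 nuclear peaks with the highest scores 14 were on X, against 33 of the other 163 (odds ratio 5.01, Fisher's exact test, p = 0.00035, a comparison chosen after the values were seen). Only 42.6% of X peaks (20 of 47) were in promoters, against 70.9% of autosomal peaks (100 of 141, odds ratio 0.30, exact p = 0.00076, also chosen afterwards). Background regions differed in the same direction, with 29.7% in promoters on X and 35.8% on the autosomes. Against its own background the odds ratio of promoters was 1.75 on X, which did not pass (exact test, adjusted p = 0.27), and 4.38 on the autosomes (adjusted p = 2.99e-16), and these odds ratios differed (two-sided z test of log odds ratios, p = 0.0091). Intergenic summits made up 36.2% of X peaks and 28.7% of X background regions (exact test, adjusted p = 0.36).

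The single highest nuclear peak, on chromosome II from 10563496 to 10563602 with a score of 116.3, was 153 bp upstream of cdc-48.1, which encodes the AAA ATPase that extracts ubiquitinated proteins. At 107 bp this region was the narrowest of the 210, of which 90.5% were 376 bp wide, and the cause was not tested. The third was at rpl-3, a ribosomal protein gene (score 103.4). Between them came an intergenic X peak with its summit at 4209299 (score 111.3), 1814 bp from F20B6.9. Other intergenic or intronic X summits near the top were at 9465842 (103.3), 11094205 (98.8), 6296544 within an intron of mom-1 (98.2), 8036417 (90.4, 4896 bp from xol-1, the switch gene of sex determination), 2997151 (88.7), 16682101 (78.4), 13700816 (74.3) and 11937556 (72.8). X promoters among the 25 belonged to puf-9, a Pumilio-family RNA-binding protein gene (93.6), nspc-17 (81.8), bet-2, which encodes a bromodomain protein (81.0), ins-39, an insulin-like peptide gene (75.6), and ftt-2, a 14-3-3 protein gene (67.5). On the autosomes, the 25 included H41C03.3 (98.97, beside the SL2 RNA gene sls-2.1), egg-5 (90.4, beside sls-2.4), tasp-1 (80.9), Y55F3AR.2 with its divergent neighbour cct-8, a chaperonin subunit gene (79.1), rpl-35 (70.3), hsp-60, the mitochondrial chaperonin gene (69.8), and rpl-20 (66.6). The summit named by hsp-60 lay 612 bp upstream of it and only 201 bp upstream of Y22D7AL.10, the nearest gene. Those named by cdc-48.1, puf-9 and tasp-1 also lay in the promoters of C06A1.7, dct-11 and K01G5.10. The summit named by rpl-20 also lay in those of Y17G9B.5 and cyc-2.1. An intronic summit in dhc-4, beside the snRNA gene R07E5.16, scored 71.8, and 1 in a noncoding exon, 4803 bp from the calmodulin gene cmd-1, scored 74.3. The rule set beforehand yielded the 22 mitochondrial peaks, described above only as a group, and the first 3 of these 25 nuclear peaks.

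Ribosomal protein genes stood out among the bound promoters. Of 78 such genes 13 (16.7%) had a promoter peak, against 0.88% of all other genes (odds ratio 22.5, Fisher's exact test, adjusted p = 9.30e-12 over 24 lists), and 0.49 genes were found on average when regions were drawn from the background. The 6 with the highest scores were rpl-3 (chromosome III, 3867854 to 3869587, summit 265 bp upstream, score 103.4), rpl-35 (III, 7855134 to 7855646, 70.3), rpl-20 (IV, 4749123 to 4749778, 66.6), rpl-15 (IV, 653480 to 654576, 63.1), rps-19 (I, 9625049 to 9625796, 58.9) and rps-20 (I, 14468332 to 14469103, 57.6). At rpl-3 the scores were 47.5 in replicate 1 and 46.6 in replicate 2, and at rpl-15 they were 44.01 and 14.5. At rpl-20, rps-19 and rps-20 the 5′ end nearest to the summit was that of another gene, Y17G9B.5, hsr-9 and ekl-4. With each peak given to its nearest gene, 8 of 78 were bound (10.3%, odds ratio 12.95, exact test, adjusted p = 1.33e-05). The odds ratio was 12.5 among genes with a pooled region in the promoter and 43.4 with the stronger 105 peaks. The list passed with the top regions of either replicate alone, with 11 and 14 genes. A summit in a ribosomal protein promoter was found in 6.91% of nuclear peaks, 0.90% of the strongest 1000 background regions and 0.25% of all background regions.

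Of 8 components of MuvB and DREAM, complexes that repress cell cycle and germline genes, lin-54 (score 53.3) and lin-9 (36.5) had a promoter peak (odds ratio 35.4, Fisher's exact test, adjusted p = 0.019). The lin-54 summit lay 325 bp upstream of lin-54 and 68 bp upstream of rpl-12, so this peak was counted in both lists. The MuvB call of the exact test was lost when each peak was given to its nearest gene, with 1 of 8 (adjusted p = 0.34), without replicate 1, also with 1 of 8 (adjusted p = 0.56), with the stronger 105 peaks, again 1 of 8 (adjusted p = 0.27), and among genes with a pooled region in the promoter, with 2 of 6 (adjusted p = 0.077). None of 1171 serpentine receptor genes, a large chemosensory family, had a promoter peak, against 1.00% of other genes (exact test, adjusted p = 0.00031), but draws from background regions gave a mean of only 3.19 and did not pass (adjusted p = 0.55). Histone genes had 3 of 72, his-67 and his-68 (1 shared peak, 40.8) and his-37 (39.7), with an adjusted p of 0.18.

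The lists for the nervous system and other tissues held almost no peaks. Among 22 pan-neuronal genes egl-3, a neuropeptide-processing protease gene, had a peak 1053 bp upstream (score 40.5, adjusted p of the list 0.63). None of 17 neurogenic transcription factors, ztf-11 included, and none of 22 regulators of neuron identity had a promoter peak. The same was true of genes of the epidermis and seam (0 of 26), body muscle (0 of 20), pharynx (0 of 10), intestine (0 of 18), germline (0 of 18) and glia (0 of 12). It was also true of the Notch pathway (0 of 20), Hox genes (0 of 6), SIN3 complex components (0 of 6), cell cycle and replication genes (0 of 26), collagens (0 of 156) and homeobox genes with ceh names (0 of 63). A single gene was bound in the Wnt pathway (mig-5, 42.9, of 25), the heterochronic genes (lin-41, 33.8, present in the list of replicate 1 only, of 16), the hlh genes (hlh-11, 43.5, of 25) and the neuropeptide genes (ins-39, 75.6, of 140), and nhr-192 (37.2) and nhr-142 (34.9) were bound among 269 nuclear hormone receptors. None of these lists passed, the smallest adjusted p being 0.63. With 188 of 19973 genes bound (0.94%), a list of about 20 genes would hold a bound gene by chance only rarely, so a count of 0 in these lists could not have passed the test.

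**Figure D3:**
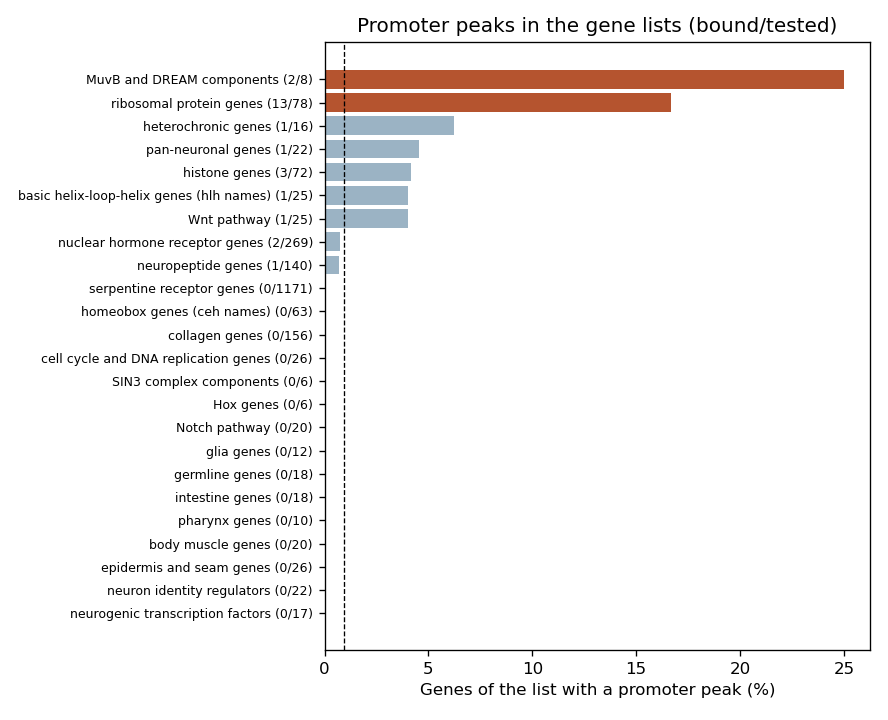
Percentage of the tested genes of each list with a promoter peak (bars; bound and tested genes in brackets); dark bars passed an adjusted p of 0.05, and the dashed line is the rate in genes outside the collagen list. Ribosomal protein genes (16.7%) and MuvB and DREAM components (25%) rise above the rest, and the serpentine receptors, which passed in the lower direction, are at 0.

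The core known for MYT1-family zinc fingers was scarcer at summits than beside them. AAAGTT, on either strand, occurred within 50 bp of the summit in 7 of 188 nuclear peaks (3.72%, 95% Wilson interval 1.82 to 7.48), against 17.02% and 15.96% in the windows centred 250 bp to either side (exact McNemar test, two-sided, p = 1.09e-05 and 6.62e-05) and 20.2% of background regions (Fisher's exact test, p = 8.87e-11). With mitochondrial peaks the share was 5.71% (12 of 210), against 15.7% and 16.7% in the flanks (exact p = 0.0011 and 0.00043). Mean GC content was 48.8% ± 8.03 (SD) around the 188 nuclear summits and 33.5% ± 9.14 around the background summits. Against background windows matched on GC content, AAAGTT was present in 3.72% of nuclear peaks and 8.62% of windows (odds ratio 0.41, unadjusted exact p = 0.017, adjusted p = 0.26 over 2080 6-mers). The lower share therefore held against the flanks and the unmatched background. Neither was matched on GC content, which is not given for the flanks. These comparisons therefore cannot separate the core from base composition. With GC matched the lower share did not pass after adjustment over 2080 6-mers, an adjustment that the other comparisons did not carry. With mitochondrial peaks included, windows of 25 bp (3.33% against 7.38% in the flanks, p = 0.13) and the stronger 105 peaks (6.67% against 17.1%, p = 0.12) did not pass the exact test against both flanks, although the shares stayed lower at the summit. All 22 mitochondrial peaks are among these 105, so 6.67% is not the share at strong nuclear peaks.

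**Figure D4:**
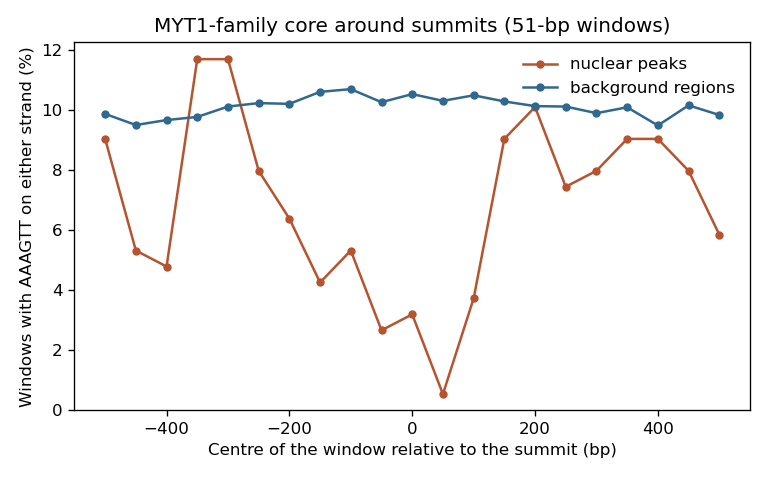
Percentage of windows (25 bp to either side of the centre) with AAAGTT on either strand, by distance of the window's centre from the summit in bp, for the 188 nuclear peaks and the 19978 background regions. Background regions stay near 10.5% at the summit, while nuclear peaks are at 3.19% there.

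Other sequences marked the summits. Of 2080 6-mers, 38 were more frequent and 13 less frequent at the 210 summits than in 2100 GC-matched background windows (Fisher's exact test, adjusted p under 0.05). For the nuclear peaks these counts were 36 and 6. The leading ones were GC-rich. GCGCGA was present in 13.8% of peaks against 3.71% of background windows (odds ratio 4.15, exact test, adjusted p = 4.61e-05), CGCGCA in 15.2% against 5.33% (adjusted p = 0.00067), ATCGCG in 9.52% against 2.33%, CGCACA in 13.3% against 5.10% and CCTGCG in 10% against 3.33%. AGAGAG, a GA repeat, was present in 24.3% against 11.7% (exact test, adjusted p = 0.0011) and AAGAGA in 22.9% against 11.5%, and GTTAGA in 8.57% against 2.48%. GGAGCC, in none of the peaks and 6.10% of windows, and GAGCAA, in 0.48% and 6.43%, were less frequent. The number of 6-mers past the threshold depended on the setting, with 28 without replicate 1 and 19 without replicate 2, of which 17 and 12 were among the 51.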

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

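The settings that use nuclear peaks alone, and the chromosome counts of each replicate alone, were chosen after seeing the data. Of 56 alternative values of the main results 40 were labelled unchanged, 14 moved and 2 lost their call, and none reversed. Unchanged meant the same side of the threshold for a test, within its error for a replicate measure, or of similar size for a count. A count can stay similar while a member loses its call, as the MuvB list did. Among 297 values for single lists, chromosomes, position classes and 6-mers, 256 were unchanged, 21 lost their call, 1 gained it and 19 changed side. The promoter share kept its excess in every alternative run (50% to 75.2%), and ribosomal protein genes passed in all of theirs (odds ratio 12.5 to 43.4). The stronger peaks number 105 by construction. The share of top regions found in both replicates was 61.9% with the list length divided by 2, 34.8% with it doubled, 11.8% with 5000 regions, 40.95% with summits within 100 bp and 40.4% with nuclear regions; the cause was not tested. The Spearman correlation of scores was 0.27 over nuclear peaks. Chromosomes past the threshold fell from 2 (X and V) to between 0 and 1 with a replicate left out (IV without replicate 1), and V stood between 0.65 and 1.00 times its share. Gene lists past it fell from 3 to 1 with the stronger peaks, which bind fewer genes. AAAGTT lost its call with windows of 25 bp (3.33%, flanks 7.38%) and the stronger peaks (6.67%, flanks 17.1%), both with fewer windows that hold it. Both settings include the mitochondrial peaks, and neither test was run on nuclear peaks alone. 6-mers past the threshold rose from 51 to 97 with 100 bp windows and 451 without GC matching, and were 19 to 28 with either replicate left out; the cause was not tested.

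Lists that passed in no setting changed side of an odds ratio of 1 in some, always on 0 to 3 bound genes. It was 0 for pan-neuronal and heterochronic genes with the 500 bp promoter, the stronger peaks and without replicate 1, for histone genes with the stronger peaks, and for histone and hlh genes without replicate 1; without replicate 2 it was 5.26, 7.34, 4.85 (histone) and 4.60 (hlh). With the nearest gene it was 6.83 for neurogenic factors, 5.75 for body muscle and Notch genes, 1.42 for collagens and 2.40 for neuropeptides, which were at 1.67 with the stronger peaks. It was 1.25 for nuclear hormone receptors with the 500 bp promoter, and 1.79 for ceh genes without replicate 1 and 4.42 for cell cycle genes without replicate 2. Reads per replicate are unknown, so what depth limits could not be judged.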

Other observations

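The tests of gene classes and of the X and mitochondrial peaks were chosen after their results were seen, and those of ribosomal protein promoters after the main results but before their own outcome was known. Peaks gathered at genes for small nuclear RNAs. Of the 188 nuclear peaks 7 (3.72%) had a summit within 200 bp of an snRNA gene, against 0.10% of background regions (odds ratio 38.6, Fisher's exact test, adjusted p = 2.91e-08 over 7 gene classes). These included sls-2.1 (chromosome II, 5844865 to 5844974, score 98.97), sls-2.4 (I, 4172206 to 4172315, with peaks of 90.4 and 59.0) and sls-2.2 (II, 5543598 to 5543707, 51.1), which encode SL2 spliced leader RNAs, and R07E5.16 (III, 10989679 to 10989780, 71.8). The peaks described above by H41C03.3, egg-5 and dhc-4 were those at sls-2.1, sls-2.4 and R07E5.16. Another 7 peaks lay at snoRNA genes (3.72% against 0.35%, exact test, adjusted p = 2.66e-05). A further 8 lay at tRNA genes (4.26% against 0.77%, exact test, adjusted p = 0.00033), and all 8 were on X, which has 276 of the 634 annotated tRNA genes. No peak lay at a piRNA gene, against 4.54% of background regions (exact test, adjusted p = 0.00050). MicroRNA genes (1 peak), long intergenic RNA genes (2) and pseudogenes (0) did not pass, with adjusted p of 0.24, 0.15 and 0.078. These comparisons with background were not matched on GC content, promoter share or score, and every background region scored lower than any peak. They cannot separate the gene classes from those properties. The peaks at sls-2.4 overlap and are not independent. Spliced leader, snRNA and tRNA genes exist in near-identical copies, among which reads cannot always be placed.

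The X peaks hold a sequence known from dosage compensation. In hermaphrodites a condensin-like complex loads on X at recruitment sites that carry the 12 bp MEX element, TCGCGCAGGGAG. The 6-mers GCGCGA, CGCGCA and CCTGCG, found at summits, occur in it on 1 strand or the other. CCTGCG was in 29.8% of X peaks against 4.96% of autosomal peaks (Fisher's exact test, adjusted p = 8.28e-05 over 4 6-mers compared). GCGCGA (25.5% against 12.1%, adjusted p = 0.071) and CGCGCA (23.4% against 14.9%, adjusted p = 0.25) did not pass the exact test, and 17 of the 29 and 21 of the 32 nuclear peaks that hold them were autosomal. Within 100 bp of the summit and with up to 2 mismatches the element was present in 14 of 47 X peaks (29.8%), against 18 of 3352 X background regions (0.54%, odds ratio 78.6, Fisher's exact test, p = 4.45e-19) and 1 of 141 autosomal peaks (0.71%, p = 8.76e-09). The comparison with background was not matched on GC content, which averaged 48.8% around nuclear summits and 33.5% around background summits. With up to 1 mismatch the element was in 10 X peaks, 2 X background regions and no autosomal peak. How far it was confined to X depended on the number of mismatches: with up to 3 it was in 22 X peaks (46.8%) and 21 autosomal peaks (14.9%), and the odds ratio between them fell from 59.4 with up to 2 to 5.03 (exact test, p = 3.11e-05). The 2 exact copies on X, with none in autosomal peaks, did not pass (exact test, p = 0.061). An exact copy lay at 11094123 to 11094134 under the intergenic summit at 11094205 (98.8) and at 2997121 to 2997132 under the summit at 2997151 within Y41G9A.17 (88.7). Copies with 1 mismatch lay under the summits at 4209299 (TCGCGAAGGGAG), in mom-1 (TCGCGCAGGGAA), near xol-1 (TCGCGCAGGGAA) and by nspc-17 (TCGCGCAGGGAC). The 14 X peaks with the element had a median score of 77.0, against 41.5 for the other 33 (permutation test, 100000 resamples, two-sided, p = 0.00077), 8 of the 12 highest X peaks carried it, and 11 of the 14 lay outside promoters. All 14 were in both replicates' lists, but so were 96.3% of nuclear peaks, so this does not set them apart.

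A hypothesis is therefore that part of the X excess may come from sites of the dosage compensation machinery, where the element with up to 2 mismatches is in 29.8% of X peaks. The 8 X peaks at tRNA genes were none of those with the element, and their part in the excess was not tested. Background regions were not more numerous on X, which held 0.95 times as many as its share of sequence. That count does not measure read density, so reads raised along the whole X chromosome were not excluded. Whether ZTF-11 itself is at these sites, or whether they are sites where many proteins are recovered, stays open, as no untagged strain or other factor was analysed here.

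The mitochondrial peaks are a candidate for a read density effect of a genome present in many copies per cell. All 22 mitochondrial regions of the pooled list passed the authors' threshold, against 0.93% of 20201 nuclear ones, and they covered 60.0% of the chromosome, with no gap over 838 bp, where nuclear peaks covered 0.070% of the nuclear genome. A few discrete binding sites would have left most of the chromosome free. The control should remove such density only where it holds as much mitochondrial DNA, which the lists do not show. The values on passing and coverage come from the peaks that prompted the read density explanation, so they are no independent test of it. No biological explanation was tested.

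At ribosomal protein promoters, draws of 188 background regions fell short of the 13 ribosomal protein genes observed. Those matched on GC content gave at most 8 in 10000 draws (mean 1.18). Those with as many promoter regions as the peaks gave at most 6 in 10000 draws (mean 0.92). Among background regions, GC content or promoter preference alone thus did not yield the observed number. All these regions score lower than any peak, and the draws were not matched on score. They therefore cannot separate these 2 explanations from an effect of score. An effect of high read density in general cannot be told apart from binding. The lower share in the strongest 1000 background regions (0.90%, against 6.91% of peaks, odds ratio 8.18, Fisher's exact test, p = 3.56e-06) had been taken beforehand as evidence against it, but those regions score lower than any peak. At neighbouring scores, a comparison chosen after this result, the shares were equal, with 2 of the 94 weaker peaks (2.13%, scores 32.9 to 40.5) and 4 of the 188 strongest background regions (2.13%, scores 25.7 to 32.8), against 11 of the 94 stronger peaks (11.7%). On these few genes the share followed the score with no step at the threshold, which keeps that explanation open.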
